A study of Drosophila melanogaster with 12 samples.

How the data were processed

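The libraries were simulated in silico, per the labels, to model Drosophila S2 cells with the splicing factor PSI knocked down, and control cells given a non-targeting siRNA. There were 3 simulated replicates in each of 4 groups, 12 libraries in all. The submitters' processing notes name STAR 2.5.4b, Cufflinks and the genome build dm3, without saying which step used which. The simulator, the read depth, the program versions and the settings of the splicing programs are not given in the sources used here.

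The authors deposited, for each of 6 programs and 3 levels, a table with a gene, a score and a class label, 18 tables in all, and the lists of AS and non-AS genes. Each score column is used as deposited by the authors, on the scale its values show, with higher meaning stronger evidence of a splicing change. JUM, rMATS and Cufflinks scores run up to 1 and were read as 1 minus a p-value or q-value. MAJIQ and Whippet scores were read as probabilities and MISO scores as Bayes factors. These readings come from the values and the usual output of the programs, since the labels do not state them. Which scores were adjusted for multiple testing is not stated either, so a threshold need not be equally strict at each level. Between 8 and 10 rMATS genes per level carry negative whole numbers outside that scale, and they were kept at the bottom of the ranking. The label column matched the lists for every gene, and each gene had 1 row per table, so the alternatives planned for these choices change nothing. Each table pools 3 knockdown and 3 control libraries, so values per library, leave-one-out fits and regrouped samples were not possible, and the precision per library is unknown.

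AUROC was computed with ties counted as 0.5 over the 16595 genes of both lists, unlisted genes tied below all others. Intervals are 95% percentile intervals from 2000 bootstrap resamples of genes, drawn within each list. Two-sided p-values came from 100000 permutations of the class (10000 for alternatives), adjusted by Benjamini-Hochberg over 18 values. Differences between JUM and the other programs were tested with 10000 exchanges of the pair's ranks per gene, adjusted over 15 comparisons. Recall at a 5% false positive rate used the lowest score that at most 5% of non-AS-list genes reach. The customary thresholds were 0.95 for scores from 0 to 1 and a Bayes factor of 10 for MISO. Shares have exact Clopper-Pearson intervals, calls on the same genes were compared with exact McNemar tests, and overlaps with 1000 permutations among listed genes. Structure was tested with 100000 permutations of the difference in medians (18 tests), and 13 gene groups with Fisher's exact test. The p-values treat genes as independent and measure neither replicate spread nor variation between simulations.

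Gene names were matched to the Ensembl release 115 annotation of BDGP6.54 by current symbol (12402 genes) or a unique older symbol (3931), together 16333 of 16595 genes (98.4%). Coordinates and transcript structure come from that annotation and not from dm3. An intron chain is a distinct set of introns among a gene's transcripts, and genes without introns were grouped with those that have 1 chain. Overlap of genes means overlap of their spans on either strand.

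The main tests, the gene groups, the thresholds and the rule for named genes were fixed before the data were examined. The comparison of recall by intron chain, the tests of JUM against other programs and between levels at the customary threshold, and AUROC of listed genes between levels were added after the data were seen. Per level the rule took 8 AS-list genes detected by the most programs with ties broken by mean rank, 6 detected by JUM alone, 4 missed by JUM and found by the most others, and 6 non-AS-list genes called by the most programs. It added Psi, up to 4 AS-list members of each group, and 4 AS-list genes detected by no program. A single gene among those the rule takes is not reported here. The rMATS genes with negative scores were chosen after their values were seen. Alternatives covered the gene universe, the rank of unlisted genes, the false positive rate, the thresholds, the pair of levels and the number of programs.

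The statistics were tested on simulated scores: over 12 settings with 16595 genes the mean AUROC missed its known value by at most 0.00221. Of 100 null pairs of 3000 genes the exchange test gave p under 0.05 in 1%, and it found all of 20 pairs with a better program. These pairs held no unlisted or tied genes, unlike the deposited scores. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.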

Results

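The data were computer-simulated RNA sequencing libraries that model Drosophila S2 cells, an embryonic line with hemocyte-like properties, after loss of the splicing factor PSI. PSI is an RNA-binding protein known for repressing splicing of the P-element transposase transcript. No cell was treated in these libraries, so the values describe how splicing programs recovered a known answer and not what PSI does in cells. The design held 12 simulated libraries: 3 of a control with a non-targeting siRNA and 3 at each of the 60%, 40% and 20% levels of simulated splicing change. All 3 levels were set against the same 3 control libraries. The deposited tables gave 1 score per gene for 6 programs (JUM, MAJIQ, rMATS, Whippet, Cufflinks and MISO) at each level, together with a list of 2000 genes called alternatively spliced (AS list) and a list of 14595 genes called not so (non-AS list). Each table pools 3 knockdown and 3 control libraries, so no spread between replicates could be computed and the depth per library is unknown. Intervals below cover the sampling of genes only, and genes are not replicates of the simulation.

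Psi itself lies on the non-AS list (FlyBase gene FBgn0014870, arm 2R, 16861321 to 16867714 in the BDGP6.54 annotation, 3 annotated intron chains). In the authors' deposited table only Cufflinks listed Psi, with a score of 0 at the 60%, 40% and 20% levels. The tables carry splicing scores and no expression level, so the knockdown of Psi cannot be read from them.

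At the 60% level and a false positive rate of 5%, 74 AS-list genes were detected by all 6 programs. The 8 of these with the highest mean rank over the programs were CG32809, CG3630, KrT95D, Tl, iPLA2-VIA, Adf1, Pka-R2 and l(2)gl. At this rate every gene in the MISO table counts as detected, whatever its Bayes factor. Tl encodes the Toll receptor of dorsoventral patterning and innate immunity and lies on arm 3R, 26799041 to 26842403, with 2 annotated intron chains. Pka-R2 encodes a regulatory subunit of protein kinase A, and Adf1 a transcription factor. iPLA2-VIA encodes a phospholipase and l(2)gl a cell polarity protein. At the 60% level Tl, in the authors' deposited table, scored 1 with JUM, MAJIQ, rMATS and Whippet, 0.999741 with Cufflinks and a Bayes factor of 1e+12 with MISO. At the 20% level the authors' deposited table still gave Tl a score of 1 with the same 4 programs and 0.998743 with Cufflinks, while its MISO Bayes factor was 0.42. CG32809 moved more: in the authors' deposited table its MAJIQ score was 1 at the 60% level and 0.696861 at the 20% level, and its Cufflinks score was 0.999741 and 0.361863. By the same ranking the first genes at the 40% level were iPLA2-VIA, Pka-R2, Tl, Adf1, G9a, CG6701, CG3764 and Df31. At the 20% level they were Ect4, Tsp26A, iPLA2-VIA, CG6701, CG10417, Tl, RpL10Ab and RpS9.

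The first comparison asked how well each program's score separated AS-list from non-AS-list genes, measured as the area under the ROC curve (AUROC), where 0.5 is chance. Over all 16595 genes, with genes missing from a table ranked last, Whippet reached 0.833 at the 60% level (95% bootstrap interval 0.823 to 0.844). Cufflinks followed with 0.654 (0.643 to 0.666), MAJIQ with 0.652 (0.640 to 0.663), JUM with 0.632 (0.621 to 0.642), rMATS with 0.606 (0.596 to 0.616) and MISO with 0.525 (0.519 to 0.530). All 18 values lay above 0.5 (two-sided label permutation test, adjusted p = 1e-05, the smallest that the permutations can give). These areas and their test depend strongly on which genes a table holds, and not on the scores alone. Whippet listed 1536 of the AS-list genes (76.8%) and 14.3% of the non-AS-list genes at the 60% level, while JUM listed 616 (30.8%) and 6.16%. MISO listed 127 AS-list genes (6.35%), and Cufflinks listed 1822 (91.1%) together with 85.9% of the non-AS list.

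Among the genes in a program's own table the order was different. JUM reached 0.945 at the 60% level (0.930 to 0.959), rMATS 0.881 (0.858 to 0.905), MAJIQ 0.860 (0.838 to 0.882), Whippet 0.691 (0.671 to 0.711) and Cufflinks 0.664 (0.653 to 0.675). MISO reached 0.527 (0.458 to 0.592), which did not differ from chance (adjusted p = 0.44, permutation test over 127 and 202 genes). These sets of genes differ between programs, so the values are not a like-for-like comparison. Over the 411 AS-list and 576 non-AS-list genes that all programs but MISO listed at the 60% level, a set chosen after the data were seen, the AUROC was 0.984 for Whippet, 0.979 for MAJIQ, 0.974 for JUM, 0.926 for rMATS and 0.917 for Cufflinks. On such genes MAJIQ was highest at the 40% level (0.981, JUM 0.973) and the 20% level (0.966, JUM 0.958). Over the 88 and 121 genes that all 6 listed at the 60% level, MAJIQ reached 0.992 and JUM 0.985, while JUM was highest at the 40% level (0.995, MAJIQ 0.9896) and the 20% level (0.972, MAJIQ 0.966). Differences within these sets were not tested.

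**Figure D1:**
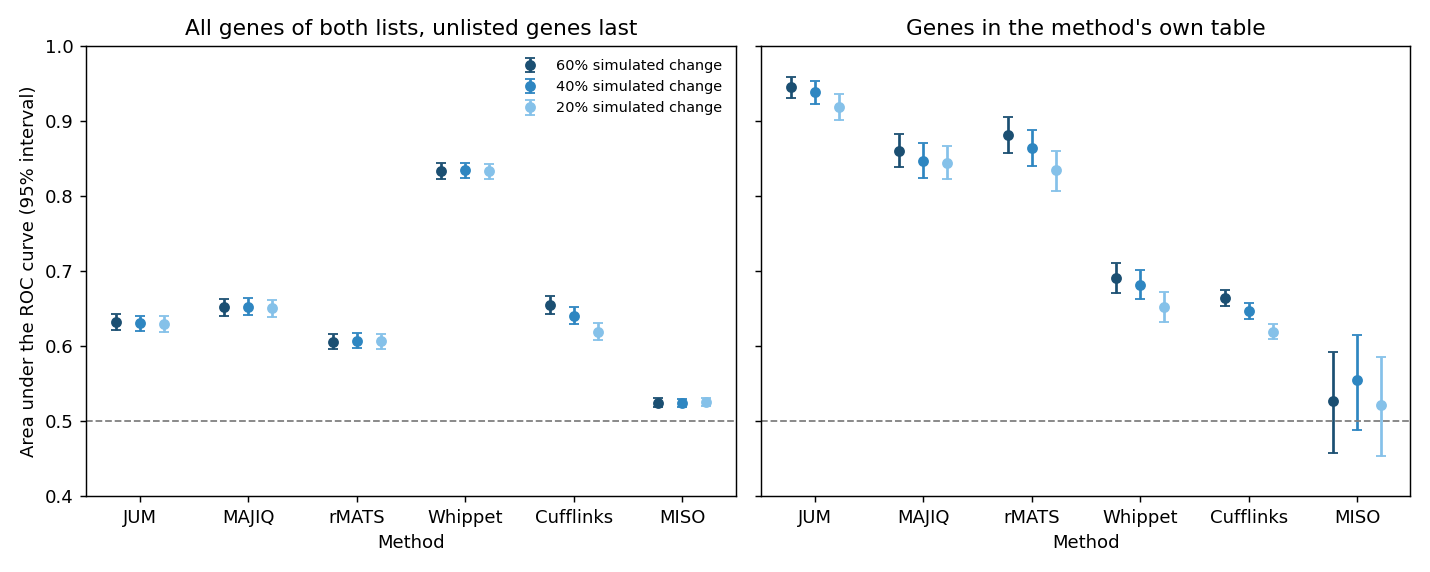
Area under the ROC curve (vertical axis) per program (horizontal axis) at 60%, 40% and 20% simulated change, with 95% bootstrap intervals over genes. Left, all genes of both lists with unlisted genes ranked last, where Whippet is highest at 0.833; right, the genes in each program's own table, where JUM is highest at 0.945 on sets of genes that differ between programs; the dashed line marks chance.

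On the genes that both programs of a pair listed, JUM and MAJIQ were not told apart. At the 60% level their AUROC differed by 0.00221 (JUM minus MAJIQ, 95% interval -0.00984 to 0.0144, adjusted p = 0.77, two-sided exchange permutation test) over 592 AS-list and 830 non-AS-list genes. JUM and Whippet differed by 0.00262 (-0.0140 to 0.0204, adjusted p = 0.77, same permutation test) at the 60% level and by 0.0210 (0.00116 to 0.0409, adjusted p = 0.073) at the 20% level. JUM was higher than rMATS by 0.0442 (0.0242 to 0.0651, permutation test, adjusted p = 0.00067) at the 60% level and by 0.0566 (0.0336 to 0.0820, adjusted p = 0.00019) at the 20% level. It was higher than Cufflinks by 0.1004 (0.0792 to 0.122) at the 60% level and by 0.151 (0.126 to 0.176) at the 20% level (permutation test, adjusted p = 0.00019 for each). It was higher than MISO by 0.446 (0.370 to 0.523, permutation test, adjusted p = 0.00019) over 108 AS-list and 158 non-AS-list genes at the 60% level.

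Over all genes of both lists, unlisted genes rank last, so the differences reflect which genes each program listed as well as its scores. The test does not separate these. Whippet listed 76.8% of the AS-list and 14.3% of the non-AS-list genes at the 60% level, and JUM 30.8% and 6.16%. JUM minus Whippet was -0.202 at the 60% level (-0.213 to -0.191, permutation test, adjusted p = 0.00012, from a raw p of 0.0001, the smallest that the permutations can give). JUM minus MAJIQ was -0.0201 (-0.0265 to -0.0139, permutation test, adjusted p = 0.00012), and JUM minus rMATS was 0.0256 (0.0167 to 0.0340, adjusted p = 0.00012). JUM minus Cufflinks was -0.0228 (-0.0348 to -0.0110, permutation test, adjusted p = 0.026) at the 60% level and 0.0105 (-0.00158 to 0.0222, adjusted p = 0.3) at the 20% level. The call at the 60% level was lost over genes listed by any program (0.000288, permutation test, adjusted p = 0.98). The sign turned over genes with 2 or more intron chains (0.0488, permutation test, adjusted p = 0.00032), as it did over genes that both listed. JUM minus MISO was 0.107 (0.0960 to 0.117, permutation test, adjusted p = 0.00012). In simulated data the exchange test gave a p under 0.05 in 1% of 100 null pairs. Those scores held no unlisted or tied genes, so its error rate on tables like these was not tested.

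The second comparison counted genes past a customary threshold of each score. Whippet called 866 AS-list genes at the 60% level, a recall of 43.3% (95% exact interval 41.1 to 45.5), MAJIQ 607 (30.4%, 28.3 to 32.4) and JUM 566 (28.3%, 26.3 to 30.3). Cufflinks called 481 (24.1%, 22.2 to 26.0), rMATS 415 (20.8%, 19.0 to 22.6) and MISO 12 (0.6%, 0.310 to 1.05). Of all genes called at the 60% level, the share on the AS list was 94.1% for Cufflinks (91.7 to 96.0), 92.2% for MAJIQ (89.9 to 94.2) and 92.2% for rMATS (89.3 to 94.5). It was 90.7% for Whippet (88.7 to 92.4), 86.3% for JUM (83.4 to 88.8) and 66.7% for MISO (41.0 to 86.7, 18 genes). These shares hold for a universe in which 12.1% of the genes are on the AS list. JUM called 208 AS-list genes that rMATS did not, and rMATS called 57 that JUM did not (exact McNemar test, adjusted p = 3.1e-21). Whippet called 323 that JUM did not, and JUM called 23 that Whippet did not (exact McNemar test, adjusted p = 2.1e-68). MAJIQ called 62 that JUM did not at the 60% level against 21 the other way (exact McNemar test, adjusted p = 8.1e-06). At the 20% level JUM called 174 that MAJIQ did not against 33 (exact McNemar test, adjusted p = 3.7e-24). JUM scores were read as derived from p-values or q-values and MAJIQ and Whippet scores as probabilities. The same threshold therefore need not be equally strict across programs. By rank, JUM and MAJIQ were not told apart on genes that both listed at the 20% level. Their AUROC was 0.926 and 0.934 there (exchange permutation test, adjusted p = 0.42).

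At a false positive rate of 5% over the whole non-AS list, recall at the 60% level was 47.1% for Whippet, 32.1% for MAJIQ, 31.2% for Cufflinks, 30.1% for JUM, 22.9% for rMATS and 6.35% for MISO. That rate allows 729 non-AS-list genes, which is most of the 899 such genes in the JUM table and more than the 202 in the MISO table, so the recalls of these 2 programs come close to the share of AS-list genes they listed. Tied scores stopped the calls of rMATS at 527 non-AS-list genes (3.61%) and those of Cufflinks at 225 (1.54%), and the MISO table held only 1.38%. JUM detected 2 percentage points fewer of the AS-list genes than MAJIQ (adjusted p = 0.00017, exact McNemar test), both at a rate of 4.99%. It detected 7.2 points more than rMATS (adjusted p = 3.7e-19) and 1.05 fewer than Cufflinks (adjusted p = 0.31) by the exact McNemar test, at rates that differ as given.

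**Figure D2:**
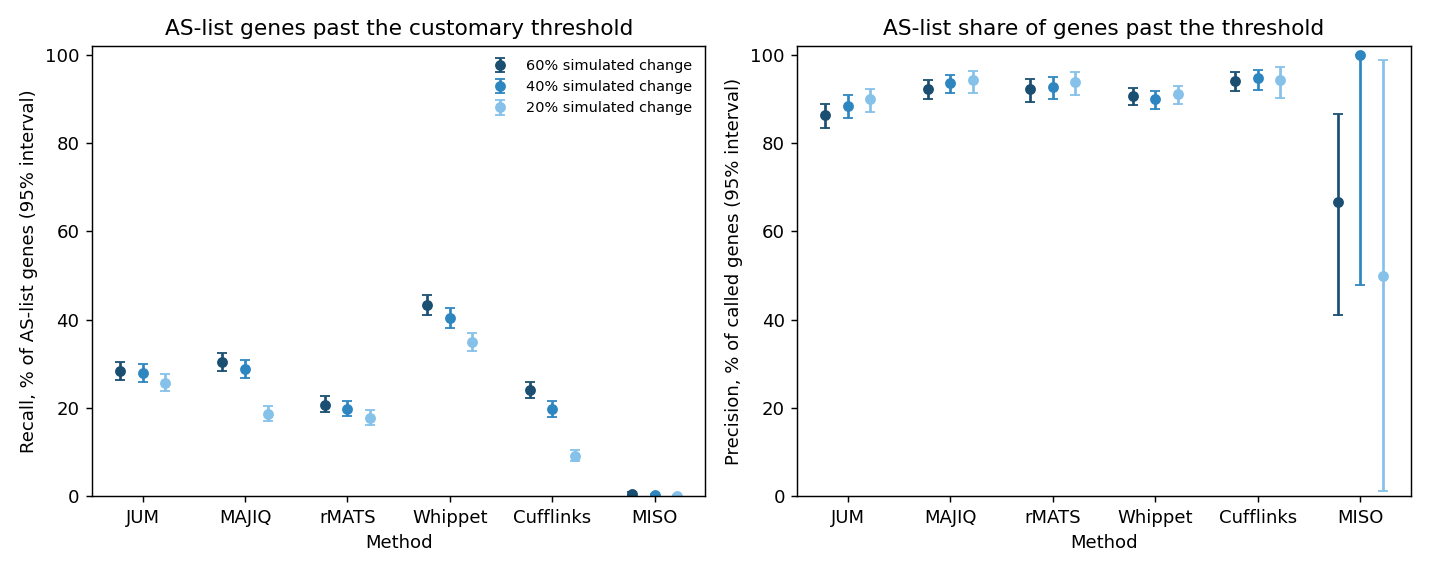
Left, recall (vertical axis, percent of 2000 AS-list genes past the customary threshold) and right, precision (vertical axis, percent of called genes that are on the AS list) per program (horizontal axis) at 60%, 40% and 20% simulated change, with exact 95% binomial intervals. Cufflinks recall goes from 24.1% to 9.2% and JUM recall from 28.3% to 25.8% between the 60% and 20% levels; the wide MISO intervals rest on 18, 5 and 2 called genes.

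The third comparison asked how the calls moved with the size of the simulated change. From the 60% to the 20% level, AS-list genes past the threshold went from 566 to 515 for JUM, 607 to 374 for MAJIQ, 415 to 354 for rMATS, 866 to 699 for Whippet, 481 to 184 for Cufflinks and 12 to 1 for MISO. Each was a fall by the exact McNemar test on the same genes, with adjusted p = 5.1e-11 for JUM, 2.6e-68 for MAJIQ, 1.7e-16 for rMATS, 2.3e-43 for Whippet, 6.6e-83 for Cufflinks and 0.00098 for MISO. Imp, an RNA-binding protein of the IGF2BP family, is an example: in the authors' deposited table its JUM, rMATS and Whippet scores were 1 at each level, while its Cufflinks score was 0.999741 at the 60% level and 0.538493 at the 20% level. The hemocyte transcription factor srp had a MAJIQ score in the authors' deposited table of 1 at the 60% level and 0.405792 at the 20% level. At the 5% false positive rate the fall passed the test for Cufflinks (623 to 451, adjusted p = 8.6e-35, exact McNemar test), Whippet (941 to 869, adjusted p = 3.2e-12) and rMATS (458 to 435, adjusted p = 0.00013). It did not pass the exact test for JUM (602 to 596, adjusted p = 0.6), MAJIQ (642 to 632, adjusted p = 0.096) or MISO (127 to 128, adjusted p = 1). At this rate MISO counts every AS-list gene it listed and JUM 602 of 616, so for these programs the counts mostly compare listing between levels and could hardly show a fall. MAJIQ counted 642 of 734 listed AS-list genes at the 60% level, at scores of 0.00148 or more. For rMATS it was 458 of 507, at 0.00163 or more, and Cufflinks counted scores from 5.9e-05. Detection at this rate thus takes little more than a listing in MAJIQ and rMATS or a score above 0 in Cufflinks. At the customary threshold recall at the 20% level was 25.8% (23.8 to 27.7) for JUM, 18.7% (17.0 to 20.5) for MAJIQ and 9.2% (7.97 to 10.6) for Cufflinks. At the 5% false positive rate it was 29.8% (27.8 to 31.9) for JUM, 31.6% (29.6 to 33.7) for MAJIQ and 22.55% (20.7 to 24.4) for Cufflinks. JUM and MAJIQ thus changed places between the 2 settings. The customary threshold need not be equally strict for the JUM and MAJIQ scores. Neither this change of places nor the size of the falls past that threshold therefore ranks these programs.

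The programs shared many AS-list genes. At the 60% level and a 5% false positive rate, the 74 AS-list genes detected by all 6 programs and 286 by 5 compare with 14.2 and 95.04 on average when each program's calls were permuted among the AS-list genes it listed (p = 0.002 for each, two-sided permutation test, the smallest that the permutations can give). At the customary threshold 7 were called by all 6 programs and 264 by 5, against 0.776 and 40.3 (permutation test, p = 0.002 for each). The permutation treats all listed AS-list genes as equally easy to detect. At that threshold and the 60% level, Cufflinks called 8.85% of its listed AS-list genes with introns and 1 intron chain, against 51.0% with 2 or more. Whippet called 28.1% and 80.4%. An excess of shared or missed genes can arise from such differences alone, so it does not by itself show agreement between programs. No program detected 962 AS-list genes (48.1%) at the 60% level and the 5% rate, against 516.8 under permutation (p = 0.002). Whippet alone detected 169, Cufflinks alone 33, MAJIQ alone 18, JUM alone 8, MISO alone 8 and rMATS alone 4. The genes that JUM alone detected at the 60% level included CG10431, CG3831, CG9706, Tbce, CR44031 and CG4751. Tbce encodes a tubulin-folding cofactor. CG10431 had in the authors' deposited table at the 60% level a JUM score of 1 and a Whippet score of 0.526, was not listed by MAJIQ, rMATS or MISO, and had a Cufflinks score of 0. At the 20% level the list also held RpS20, CR44999 and Fib, all with 1 annotated intron chain. The JUM score of Fib (fibrillarin, a nucleolar methyltransferase) in the authors' deposited table at that level was 0.386181, far under the customary threshold of 0.95.

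Some AS-list genes were missed by JUM at the 5% false positive rate and found by most of the others. At the 60% level these included Pxn, found by all 5, and CG2061 and ck, each found by 4. MISO counts for Pxn and ck by listing them, with Bayes factors of 6.79 and 1.24. Past the customary threshold Pxn was called by 4 programs and ck by 3 at that level. Pxn encodes peroxidasin, an extracellular matrix enzyme made by hemocytes, and ck an unconventional myosin. Pxn was, in the authors' deposited table, not listed by JUM at the 60% level but had a JUM score of 1 at the 40% and 20% levels. CG2061 was listed by JUM with a low score in the authors' deposited table, 0.155213 at the 60% level, while MAJIQ, rMATS and Whippet gave it 1. That JUM score lies just under the 0.157758 that counts as detected at the 5% rate. At the 40% level the genes included CG2061, CG17816 and rin, and at the 20% level they were ck, Zif, CG2061 and CG14642. Fewer programs called most of them past the customary threshold. At the 40% level CG2061 was called by 4, CG17816 by 3 and rin by 2. At the 20% level CG2061 was called by 4, Zif by 3, ck by 2 and CG14642 by 1.

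Gene groups fixed before the data were examined were looked up on the AS list. Of 84 cytoplasmic ribosomal protein genes, 21 lay on the AS list (25%, against 12.1% of all genes, odds ratio 2.45, Fisher's exact test, adjusted p = 0.0135). Of these 21, 16 were past the threshold in 1 or more programs at the 60% level and 12 in 4 or more. RpL10, RpL10Ab, RpL15 and RpS15Aa were past it in 5 programs at that level. RpL10 scored, in the authors' deposited table, 1 with JUM, MAJIQ, rMATS and Whippet at the 60%, 40% and 20% levels. The 5 ribosomal AS-list genes past the threshold in no program at any level all have 1 annotated intron chain. How genes were chosen for the list is not given in the sources used here, so its make-up is no measurement of PSI targets.

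The other 12 groups did not pass the test. Of 16 translation factors 6 lay on the AS list (odds ratio 4.39, adjusted p = 0.0501, Fisher's exact test), among them the initiation factors eIF-4a, eIF-4E and eIF5 and the poly(A)-binding protein pAbp. The first 3 were past the threshold in 5 programs at the 60% level and pAbp in 3. Of 17 hemocyte genes 6 lay on it (odds ratio 3.99, Fisher's exact test, adjusted p = 0.0501), and srp, Pxn, the collagen Cg25C and the zinc finger factor ush were past the threshold in 4 or more programs at the 60% level. Signalling genes had 8 of 31 members (odds ratio 2.54, Fisher's exact test, adjusted p = 0.0883), and 7 of these, among them Pka-R2, Pka-R1, drk and foxo, were past it in 4 or more programs at that level. The cytoskeletal group had 7 of 33 (odds ratio 1.97, Fisher's exact test, adjusted p = 0.243). All 7 were past the threshold in 4 or more programs at the 60% level, including tropomyosin Tm1, CLIP-190, Zasp52 and the actin regulator ena.

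Splicing regulators were present as simulated targets. The SR protein group had 3 of 13 members on the AS list (odds ratio 2.19, Fisher's exact test, adjusted p = 0.325): B52 and SC35, both SR proteins, were past the threshold in 5 programs at each level, and the SR protein kinase SRPK in 4 at the 60% level. SRPK scored, in the authors' deposited table, 1 with JUM, MAJIQ and Whippet and 0.985075 with Cufflinks at the 60% level, and rMATS did not list it. The hnRNP and regulator group had 6 of 25 (odds ratio 2.31, Fisher's exact test, adjusted p = 0.243), of which Imp, A2bp1, Rox8 and heph were past the threshold in 4 or more programs at the 60% level. The core spliceosome group had 3 of 22 (odds ratio 1.15, Fisher's exact test, adjusted p = 0.743), SmB, SmE and snRNP-U1-C. None of these 3 was past the threshold at any level. SmB has 1 annotated intron chain, and SmE and snRNP-U1-C have 1 annotated exon and no intron. snRNP-U1-C was also the AS-list member of the 6 genes of the PSI silencer complex (odds ratio 1.46, Fisher's exact test, adjusted p = 0.661).

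The textbook group of genes known for complex splicing had 5 of 22 on the AS list (odds ratio 2.15, Fisher's exact test, adjusted p = 0.325), Dscam1, mod(mdg4), lola, Tm1 and Nrg. Of these 5, JUM, MAJIQ and Whippet each called 5 at the 60% level, rMATS and Cufflinks 3 and MISO 0, and the differences between programs in this group were not tested. Dscam1, the cell adhesion gene known for its very large number of isoforms (75 annotated intron chains), was past the threshold in JUM, MAJIQ and Whippet at each level. Dscam1 was not, in the authors' deposited table, listed by rMATS or Cufflinks and had a MISO Bayes factor of 0 at the 60% level. lola, a BTB transcription factor, scored 1 with JUM, MAJIQ and Whippet and 0 with rMATS at the 60% level in the authors' deposited table. The chromatin and BTB group had 4 of 27 (odds ratio 1.27, Fisher's exact test, adjusted p = 0.661), with BEAF-32 past the threshold in 3 programs at the 60% level and Pc, a Polycomb protein with 1 intron chain, in none. Of markers of other cell types, 3 of 16 neuronal genes (Appl, Nrg and futsch; odds ratio 1.69, Fisher's exact test, adjusted p = 0.621) and 2 of 15 germline genes (vas and piwi; odds ratio 1.12, adjusted p = 0.743) lay on the AS list. The neuronal gene futsch had, in the authors' deposited table, a Whippet score of 1 and a JUM score of 0.107667 at the 60% level.

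Calls among non-AS-list genes were examined last. At the 60% level JUM called 90 of them, Whippet 89, MAJIQ 51, rMATS 35, Cufflinks 30 and MISO 6, and 256 genes were called by 1 or more programs. CAP, cdc14, Sxl, Rph, sea and CG5946 were called by 3 programs, against 0.498 genes with 3 or more on average under permutation (p = 0.001, one-sided permutation test, the smallest that the permutations can give). The permutation treats all listed non-AS-list genes as equally easy to call. Cufflinks scored only 225 of its 12539 above 0 at that level, so the permuted average is low. Sxl encodes an RNA-binding regulator of sex determination, sea a mitochondrial citrate carrier, cdc14 a phosphatase and Rph rabphilin. In the authors' deposited table sea scored 1 with JUM and MAJIQ at the 60% and 20% levels and 0.999741 with Cufflinks at the 60% level. Sxl had, in the authors' deposited table, JUM scores of 0.992848 at the 60% level and 0.998657 at the 20% level. CAP had a MISO Bayes factor of 1e+12 at the 60% level and 0.13 at the 40% level in the authors' deposited table. At the 40% level 5 genes were called by 3 or more programs (permutation test, p = 0.001), and the leading genes were Calx, CG5946, sdk, Sxl, Tyler and Eip71CD. At the 20% level 2 genes were (permutation test, p = 0.008), and the leading genes were Calx, sea, scrib, CG5514, dlg1 and MRP.

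Many of the same non-AS-list genes were called at more than 1 level. Of the genes that MAJIQ listed at both levels, 51 were called at the 60% level and 23 at the 20% level, and 22 were called at both, against 0.956 for independent lists. The counts called at both levels were 20 for JUM (5.37 for independent lists), 23 for Whippet (2.97), 12 for rMATS (1.09) and 5 for Cufflinks (0.0263). The levels share 3 control libraries, so part of this overlap may come from them, and no value for unchanged groups could be simulated without values per library. The numbers for independent lists also treat all listed genes as equally easy to call. The Cufflinks number is too low, as only 225 of its 12539 listed non-AS-list genes scored above 0 at the 60% level.

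Gene structure separated AS-list genes detected at a 5% false positive rate from the others in every program at the 60% level. For MISO that contrast is between listed and unlisted genes, and for JUM nearly so, since 602 of its 616 listed AS-list genes count as detected. It is largely so for rMATS (458 of 507) and MAJIQ (642 of 734). AS-list genes detected by JUM had a median of 4 annotated transcripts, 9 exons and 5636.5 bp, against 1, 4 and 2040 bp for the other AS-list genes (permutation tests, adjusted p = 1e-05 for each, the smallest that the permutations can give). For Whippet the medians were 3 transcripts, 7 exons and 4335.5 bp, against 1, 3 and 1843.5 bp. The comparison by intron chain was chosen after the data were seen. In the BDGP6.54 annotation 1130 of 1974 matched AS-list genes (57.2%) have at most 1 intron chain, that is, no annotated difference in introns between transcripts, and 196 of these have no intron at all. On the non-AS list 9862 of 14359 matched genes (68.7%) have at most 1 intron chain. Of the 1130 AS-list genes JUM called 4 (0.354%, 0.0965 to 0.904), MAJIQ 5, rMATS 3, MISO 0, Cufflinks 76 (6.73%, 5.34 to 8.35) and Whippet 214 (18.9%, 16.7 to 21.3). Among the 196 without introns Whippet called 21 and the other programs none. Among the 934 with introns and 1 chain Whippet called 20.7% (18.1 to 23.4), Cufflinks 8.14% (6.46 to 10.1) and JUM 0.428% (0.117 to 1.09). Of the 844 AS-list genes with 2 or more intron chains Whippet called 75.6% (72.5 to 78.5), MAJIQ 70.1% (66.9 to 73.2), JUM 65.5% (62.2 to 68.7), rMATS 48.1% (44.7 to 51.5), Cufflinks 47.4% (44.0 to 50.8) and MISO 1.42% (0.737 to 2.47). Aats-trp, CG10352, CG2064 and CG31999 were detected by no program at any level at a 5% false positive rate, and the first 3 have 1 intron chain. The annotation is newer than the build the submitters name, so a gene's isoforms in the simulation can differ.

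**Figure D3:**
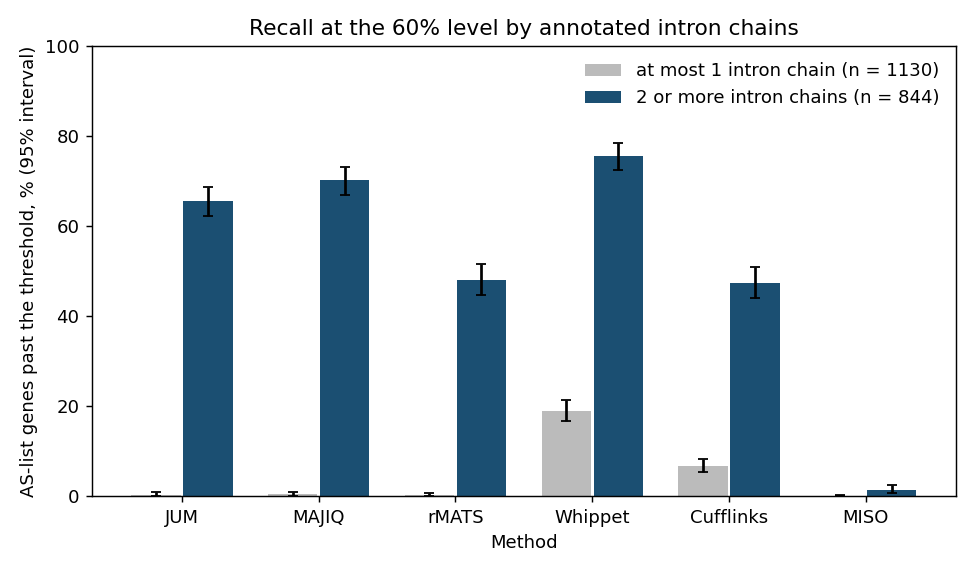
Share of AS-list genes past the customary threshold at the 60% level (vertical axis, percent, exact 95% binomial intervals) per program (horizontal axis), for genes with at most 1 annotated intron chain (grey, 1130 genes, 196 of them without introns) and with 2 or more (blue, 844 genes). Recall of JUM is 0.354% in the first set and 65.5% in the second, and Whippet reaches 18.9% and 75.6%.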

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

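The results here differed between the 60% and 20% levels. Of the tests in this part, those on counts past the customary threshold at the 2 levels and on AUROC of listed genes were chosen after the data were seen. The look at chance turnover was also added after the data were seen.

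AS-list genes past the customary threshold were more numerous at the 60% than at the 20% level, by 51 for JUM, 233 for MAJIQ, 61 for rMATS, 167 for Whippet, 297 for Cufflinks and 11 for MISO (exact McNemar tests). At a 5% false positive rate the difference passed the test for rMATS (23 genes), Whippet (72) and Cufflinks (172). AUROC over all genes was higher at the 60% level for Cufflinks, by 0.0351 (0.0293 to 0.0410). AUROC of listed genes was higher by 0.0265 for JUM, 0.0156 for MAJIQ, 0.0468 for rMATS, 0.0392 for Whippet and 0.0448 for Cufflinks, with intervals above 0.

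Non-AS-list genes past the threshold were also more numerous at the 60% level, by 32 for JUM (adjusted p = 0.0054, exact McNemar test), 28 for MAJIQ (adjusted p = 3.5e-07) and 19 for Cufflinks (adjusted p = 0.0026). The differences of 12 for rMATS (exact McNemar test, adjusted p = 0.086), 20 for Whippet (adjusted p = 0.087) and 5 for MISO (adjusted p = 0.12) did not pass. The AS-list share of called genes was 94.1% at the 60% and 94.4% at the 20% level for Cufflinks, so it hardly moved. It was 86.3% and 89.9% for JUM and 92.2% and 94.2% for MAJIQ. Chance turnover near the threshold would give about as many genes at the 20% level alone as at the 60% level alone. The counts at the 60% and the 20% level alone were 70 and 38 for JUM, 29 and 1 for MAJIQ and 25 and 6 for Cufflinks. They were 23 and 11 for rMATS, 66 and 46 for Whippet and 6 and 1 for MISO. The exact tests above already compare these counts, so they give no evidence on chance turnover beyond those differences. Reads shared with an overlapping AS-list gene may account for part. Of 191 non-AS-list genes past the threshold at the 60% but not the 20% level, 62 (32.5%) overlap an AS-list gene, against 1089 of 12186 genes (8.94%) past it at neither level (Fisher's exact test, p = 2.2e-19), or 15.7% of those listed by a program other than Cufflinks (p = 5.6e-08). The other 129 of the 191 overlap none, and some of the 62 would overlap at the base rate as well. This contrast is between called and uncalled genes, so it does not test the difference between levels. Without overlapping genes JUM called 66 non-AS-list genes at the 60% and 44 at the 20% level, against 90 and 58 with them. MAJIQ called 14 and 9, against 51 and 23. Most of the difference thus stayed for JUM and little of it for MAJIQ, and neither was tested. No biological explanation was tested, since the libraries are simulated.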

How the results depend on the processing

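No paired analysis was possible because the tables hold no values per library, and for the same reason leaving out a replicate was impossible. Alternatives on the intron chains, on genes listed by all programs but MISO, on overlapping genes, on the negative rMATS scores, on listed genes for the change across levels and on the threshold for the recall difference were chosen after seeing the data. Where a value changed, the cause was not tested, apart from settings that leave genes out by construction.

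All 18 AUROC values stayed above 0.5 and past the test with genes listed by any program and with unlisted genes tied with the lowest score, rMATS did so with negative scores left out or ranked first, and the 15 values of the other programs did so among genes listed by all programs but MISO. For MISO the test was no longer passed among listed genes (0.527, 0.554 and 0.521 at the 60%, 40% and 20% levels) and among genes listed by all 6 programs (0.511, 0.543 and 0.534). For JUM minus MAJIQ, the difference among genes listed by both was 0.00221, -0.00662 and -0.00776 at the 60%, 40% and 20% levels and no longer passed. For JUM minus Whippet it turned to 0.00262, 0.0114 and 0.0210. For JUM minus Cufflinks it was 0.1004, 0.118 and 0.151 among genes listed by both, 0.000288, 0.0153 and 0.0401 among genes listed by any program, and 0.0488, 0.0698 and 0.110 among genes with 2 or more intron chains, so the sign turned at the 60% and 40% levels and the 20% level came to pass the test.

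Recall at a false positive rate of 1% was 26.9% for JUM, 29.2% for MAJIQ and 19.7% for rMATS at the 20% level, 44.3%, 41.5% and 37.1% for Whippet and 4.5%, 4.55% and 4.95% for MISO at the 60%, 40% and 20% levels. At 10% it was 36.7%, 36.9% and 36.5% for MAJIQ, 25.4%, 25.7% and 25.6% for rMATS and 56.9%, 56.6% and 56.4% for Whippet. Listing over the union of levels gave MISO 8.3%, above its value at each level. The recall difference of JUM minus Cufflinks at the 40% level was 0.75 points at a 1% rate (exact McNemar test, adjusted p = 0.49). At the customary threshold JUM minus MAJIQ was -0.95 points at the 40% level (exact McNemar test, adjusted p = 0.067) and turned to 7.05 at the 20% level, and JUM minus Cufflinks turned to 4.25 at the 60% level.

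With stricter thresholds recall was 41%, 37.9% and 29.8% for Whippet, 15.6% for MAJIQ at the 20% level, and 17.5% and 6.15% for Cufflinks at the 40% and 20% levels. Precision was 92.4%, 94.0% and 96.0% for JUM, 94.7% and 96.0% for rMATS at the 60% and 40% levels, 96.4%, 96.9% and 96.4% for Whippet and 100% for MISO at the 20% level. With looser thresholds recall was 46.1%, 44.8% and 40.5% for Whippet, 22.4% for MAJIQ and 11.2% for Cufflinks at the 20% level. Precision was 81.7%, 81.9% and 83.8% for JUM, 88.7%, 89.4% and 90.2% for rMATS and 66.3%, 66.5% and 64.2% for Whippet. The looser threshold was 0.9 for JUM, rMATS and Cufflinks but 0.8 for MAJIQ and Whippet, so these values are not like-for-like. Among AS-list genes with 2 or more intron chains recall was 65.5%, 64.5% and 59.6% for JUM, 70.1%, 66.8% and 43.6% for MAJIQ, 48.1%, 46.0% and 41.0% for rMATS, 75.6%, 71.3% and 63.0% for Whippet, 47.4%, 40.3% and 19.9% for Cufflinks, and 1.42% and 0.592% for MISO at the 60% and 40% levels. Without non-AS-list genes that overlap an AS-list gene, precision was 89.6% for JUM at the 60% level, 97.7%, 98.5% and 97.7% for MAJIQ and 97.0% and 97.3% for Cufflinks at the 60% and 40% levels.

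The AUROC change across levels turned sign between 60% and 40% for MAJIQ (-0.000840), Whippet (-0.00101) and MISO (0.000795) and between 40% and 20% for rMATS (0.00111). Among listed genes it came to exclude 0 for JUM (0.0265), MAJIQ (0.0156) and Whippet (0.0392), and it turned sign for rMATS (0.0468) and MISO (0.00541). The change in detected AS-list genes was -1 for JUM and 10 for rMATS between 40% and 20%, and 3 for MISO between 60% and 40%. Non-AS-list genes called by 2 or more programs numbered 39, 25 and 17 at the 60%, 40% and 20% levels. The 13 gene groups kept their direction and their side of the threshold against genes listed by any program. This check is a weak one, since that background holds 14671 of the 16595 genes, with 13.1% on the AS list against 12.1%. Recall at the 5% rate among genes listed by any program stayed within its interval for all 18 values, and AS-list genes called by no program at the customary threshold numbered 1065, 1118 and 1229, within 1.5 times the counts at the 5% rate. The label column and the lowest of several entries per gene changed nothing, since labels matched the lists and each gene had 1 entry.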

Other observations

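Of the tests in this part, those on mutually exclusive exons and on intron chains were chosen after the pattern was seen.

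The 6 non-AS-list genes called by 3 programs at the 60% level overlapped AS-list genes more often than other non-AS-list genes listed by 3 or more programs. CAP, CG5946, cdc14 and sea overlap an AS-list gene, 4 of 6 against 179 of 1141 (15.7%; Fisher's exact test, p = 0.0072). Their median of 6 annotated transcripts was above the 3 of the other genes (permutation test, p = 0.023). Both properties may contribute, and with 6 genes they were not separated. Sxl and Rph overlap no AS-list gene.

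In rMATS, 10 genes carry negative whole-number scores at some level: CG40498, CG4300, Cnx99A, LM408, MRP, Mhc, Snap25, babo, laccase2 and qvr. Snap25 scored, in the authors' deposited table, -146 and babo -197 with rMATS at each level. A score placed at the bottom for genes without evidence of change was looked at through the other programs. All 4 AS-list genes among the 10 (CG4300, Snap25, babo and laccase2) were past the threshold in JUM, MAJIQ, Whippet and Cufflinks at the 60% level. The same 4 programs also called lola, which rMATS scored 0 at that level. Calls by other programs thus do not show what evidence rMATS had, and this account stays open. All 10 genes with negative scores have annotated mutually exclusive exons, against 87 of 1257 other genes that rMATS listed (6.92%; Fisher's exact test, p = 4.4e-12). A candidate explanation is that for such events the score was taken from a different column of the rMATS output, such as a form length, since 1 minus the score is then a whole number such as 198 or 147. The rMATS output itself was not analysed here.

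Past the threshold in no program at any level were 1052 AS-list genes. Absence from the tables is argued against as the whole account for the programs pooled, since 39.7% of them were listed by no program other than Cufflinks. For single programs it weighs more. Of the 1130 AS-list genes with at most 1 intron chain, Whippet listed 720 at the 60% level, but MAJIQ 90, JUM 18, MISO 16 and rMATS 12. Of the 1040 with a matched annotation, 900 (86.5%) have no intron or a single intron chain, against 230 of 934 AS-list genes called somewhere (24.6%; Fisher's exact test, p = 3.1e-182). Without the genes that have no intron, the shares were 83.8% of 865 and 22.9% of 913 (Fisher's exact test, p = 2.2e-156). A candidate explanation is that many of these genes had no alternative junction to simulate, or changed only in transcript ends. Isoforms present in the annotation used for the simulation and since withdrawn stay open, as that annotation was not used here. Whippet nevertheless called 29.7% of the AS-list genes with at most 1 intron chain that it listed, against 3.04% of such non-AS-list genes.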
